A study of Mus musculus with 6 samples.

How the data were processed

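RNA of Sca-1-selected spleen cells from 6 mice was labelled with biotin and hybridised to Affymetrix exon arrays, per the labels' protocols. The deposited values were on a log2 scale, from 2.6 to 14.3, as read from the values themselves. Per the submitters' processing notes the authors used genome build mm9. The normalization, the summarisation and any filter were not given in the sources used here, so how they shaped small differences stayed unknown. No scanner files and no background signal were used here, and the number of arrays limits the precision.

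The table held 23332 probe set entries. The platform annotation gave 1 gene symbol to 14996, several to 1019 and none to 7317, and only entries with 1 symbol were named. Of the symbols, 14941 were matched by Entrez number to a gene table of assembly GRCm38.p6, which changed 0 of them, and no coordinates were used because the builds differ. For the 135 genes with more than 1 entry, the entry with the highest mean over all arrays was kept, leaving 14860 genes. Ly6a, which encodes Sca-1, and Xist, Ddx3y and Uty were not analysed here.

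The groups came from the treatment labels, with 3 control mice and 3 treated mice, numbered in accession order. The labels number the mice differently in each group, so nothing pairs them. They are separate animals, and the p-values of single genes rest on the spread between them, with variances partly shared over genes. The groups, the tests, the gene lists, the rule for named genes and the alternatives, except those named next, were fixed before the data were examined. An alternative chosen after seeing the data tested all table entries, named or not. Another, without both control mouse 3 and treated mouse 1, was also run after seeing the data and is not reported, because treated mouse 1 had been picked for lying near the controls. The 4 lists whose counts over the list alone were followed through the alternatives were chosen after seeing the data too.

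Differences, treated minus control, were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A looser description used an unadjusted p under 0.05 with at least 1.5-fold. Lists were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry. Camera compares a list with the other genes, while fry asks whether its genes move one way on balance and, in its mixed form, whether they move in either direction. At the preset correlation, camera judges a list against the spread over genes. It then allows only slightly for members that vary together between mice. List means per mouse were compared by a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. Counts adjusted over the list alone used Benjamini-Hochberg within that list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

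The 30 tested lists covered the anti-apoptotic and pro-apoptotic BCL-2 families, caspases and apoptosome, p53 targets, DNA replication, mitosis, DNA repair and checkpoint, stem and progenitor genes, Wnt, Notch, RAS-MAPK targets, FOXO targets, NF-kB targets, interferon-stimulated genes, the unfolded protein response, immediate-early genes, oxidative phosphorylation, and glycolysis and hypoxia. The others held markers of erythroid cells, granulocytes, monocytes and macrophages, B cells, plasma cells, T cells, NK cells, dendritic cells, MHC class II presentation, megakaryocytes and platelets, mast cells and basophils, and endothelial and stromal cells. A further list of sex-linked genes was a check only.

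Genes were named by a rule with 3 parts. The first took the 10 largest differences in each direction among genes past the adjusted threshold whose groups did not overlap and whose higher mean reached the 25th percentile. As none passed, its places were filled from genes at an unadjusted p under 0.01. The second took the 3 members of each list with the smallest p, and the third took Nras, Bcl2, Bcl2l1, Bcl2l2, Mcl1, Kit, Cd34 and the sex-linked genes. Not every gene so chosen is described. Genes named as passing over a list alone, and others outside the rule, were chosen after their values were seen.

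Alternatives were quantile normalization, centring of each array on its median, leaving out the dimmest 30% of signals, trended and robust variance, array weights, the mean of a gene's entries, looser or stricter thresholds, a sex covariate, lists without shared members, and leaving out each mouse. The fit was tested on simulated data with 200 changed genes among 14860 for this comparison. At a log2 change of 1 it called 88% of 50 genes, at 2, 3 and 4 it called 100%, and it made 8 false calls. That simulation gave each gene independent noise, so it says nothing of genes that vary together between mice. It also drew the noise with variances that eBayes had already pulled towards a common value. The shares called may therefore be too high for these data, where Cxcr2, at a difference of 2.93, had an adjusted p of 0.155 by limma.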

Results

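Gene expression was measured with 1 Affymetrix exon array per mouse in spleen cells selected with magnetic beads for Sca-1, a surface marker of primitive blood cells. All 6 mice were NRASD12/BCL-2 double transgenic animals on the FVB/N background, a model of acute myeloid leukaemia. Of these, 3 were controls, untreated per the series description, and 3 had received ABT-737, a small molecule that blocks the survival proteins BCL-2, BCL-XL and BCL-W, in doses of 75 mg/kg, 3 each week, over 33 days. Whether the controls received the vehicle was not given in the sources used here. Median log2 signals were 7.13, 6.86 and 7.09 in the control mice and 7.13, 7.14 and 7.07 in the treated mice. Correlations between arrays over all values ran from 0.977 to 0.992, and no pair of arrays held the same values. The first principal component took 44.1% of the variance. Its scores were -15.0, -21.0 and -16.9 in the controls, -7.42 in treated mouse 1, and 32.2 and 28.1 in treated mice 2 and 3. The Y-linked genes Kdm5d and Eif2s3y were low in control mouse 3, at 4.77 and 4.23, and ranged from 8.05 to 9.06 and from 9.87 to 10.27 in the other mice.

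The comparison asked which genes of cell survival, proliferation and stem cells, and which other genes, differed after ABT-737. Largest differences are given under the naming rule, which asked for an unadjusted p under 0.01 and groups that did not overlap. Under it, the 10 largest positive differences included 3 genes of the granulocyte list, Cxcr2, Mmp9 and Mmp8. Cxcr2, the neutrophil receptor for CXC chemokines, stood at 8.79 ± 0.52 in the controls and 11.73 ± 0.57 in the treated mice (SD, n = 3 each), a difference of 2.93 log2 (SE 0.35, 7.64-fold; adjusted p = 0.155 by limma). Clec4d, a C-type lectin receptor of myeloid cells, was higher by 2.98 (SE 0.34, adjusted p = 0.155), and Mmp9, a gelatinase stored in neutrophil granules, by 2.91 (SE 0.39, adjusted p = 0.181). Genes with the largest negative differences included Gpr171, S1pr3, a sphingosine phosphate receptor, and Cxcr5, the receptor that guides lymphocytes into B cell follicles, which were 3.00-fold, 2.83-fold and 2.27-fold lower (SE 0.27, 0.26 and 0.28 log2). None of these genes passed the adjusted threshold of 0.05.

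Of 14860 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest was 0.114. At an unadjusted p under 0.05 there were 1516 genes, 854 higher and 662 lower. With no effect 743 would be counted on average, but other splits of the same mice into 3 and 3 gave 249 to 1279. Of the 1516 genes, 660 also differed by at least 1.5-fold, 504 higher and 156 lower. The higher share was 76.4%, and it was 62.2% after quantile normalization and 56.8% after centring each array on its median, which moved the median difference of all genes from -0.02 to -0.06 and -0.11. In 912 genes all treated mice lay above all controls and in 1068 below, together 13.3% of genes against 10% by chance on average. That share was not computed for the other splits, so it is not shown to exceed theirs. Adjusted calls numbered 14 when the dimmest 30% of signals were left out, 2 with array weights, and 510 without treated mouse 1. Without treated mouse 3 there was 1, and without any 1 of the other mice there were 0.

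The remaining 7 of the 10 largest positive differences were Dhrs9 at 2.91, Il1f9, an interleukin-1 family cytokine, at 2.82, Mmp8, a neutrophil collagenase, at 2.71, Asprv1 at 2.70, Tm4sf1 at 2.63, Steap4, a metalloreductase, at 2.50, and Slc7a11, the cystine and glutamate exchanger, at 2.42. Their adjusted p values by limma ran from 0.203 for Slc7a11 to 0.330 for Tm4sf1. The remaining 7 of the 10 largest negative differences were Hs3st1 at -1.64, Rasd1 at -1.46, Serpinb6b at -1.30, Ccr6, a chemokine receptor of lymphocytes, at -1.29, Cdh17 at -1.28, Rab30 at -1.27 and Cd83, a marker of activated B cells and dendritic cells, at -1.19. Their adjusted p values ran from 0.198 for Serpinb6b to 0.358 for Rasd1. Gzmb, at -1.48 (SE 0.52), was not counted among the largest negative differences, as its groups overlapped and its unadjusted p by limma was 0.024.

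Of 30 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 placed 15 past an adjusted p of 0.05, 10 higher and 5 lower. With the correlation estimated per list it placed 0, with 0 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.590, and fry placed 0, with a smallest adjusted p of 0.470. The mixed test of fry, which asks whether genes of a list differ in either direction, placed 5, with adjusted p of 0.000702 for NF-kB targets, 0.0303 for p53 targets, RAS-MAPK targets and mast cell genes, and 0.0381 for granulocyte genes. On simulated data with no effect, every list was given a deviation shared by its members in each mouse, as large as the gene noise. There the preset correlation called a mean of 15.7 of 30 lists. Estimated correlations in the data ran from -0.024 for the anti-apoptotic family to 0.92 for mitosis, so that number is no expected count for these lists. It shows that correlated members can give calls with no effect, so these list calls are weak evidence of a shift.

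Granulocyte genes had the largest list median. Of 22 measured, 18 were higher and 4 lower, with a median of 1.17. Adjusted over the list alone, 13 passed, all higher, among them Cxcr2, Mmp9 and Csf3r, the receptor for granulocyte colony-stimulating factor, which rose by 1.83 (SE 0.23), and over all genes 0 passed. The 4 lower members, picked out after their values were seen, were Elane, Mpo, Prtn3 and Ctsg, proteases and a peroxidase of the azurophil granules of early granulocytes, at -0.32, -0.51, -0.55 and -0.73. The list means relative to the controls were 0.42 in treated mouse 1, 1.42 and 1.65 in treated mice 2 and 3, and -0.53 in control mouse 3, the mouse with low Y-linked signal. The adjusted p with an estimated correlation was 0.590, and the exact permutation test of the list mean gave p = 0.1, the smallest that 3 against 3 allows. The number passing over the list alone was 7 without control mouse 2, 8 without control mouse 3, 6 without treated mouse 2 and 7 without treated mouse 3.

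**Figure D1:**
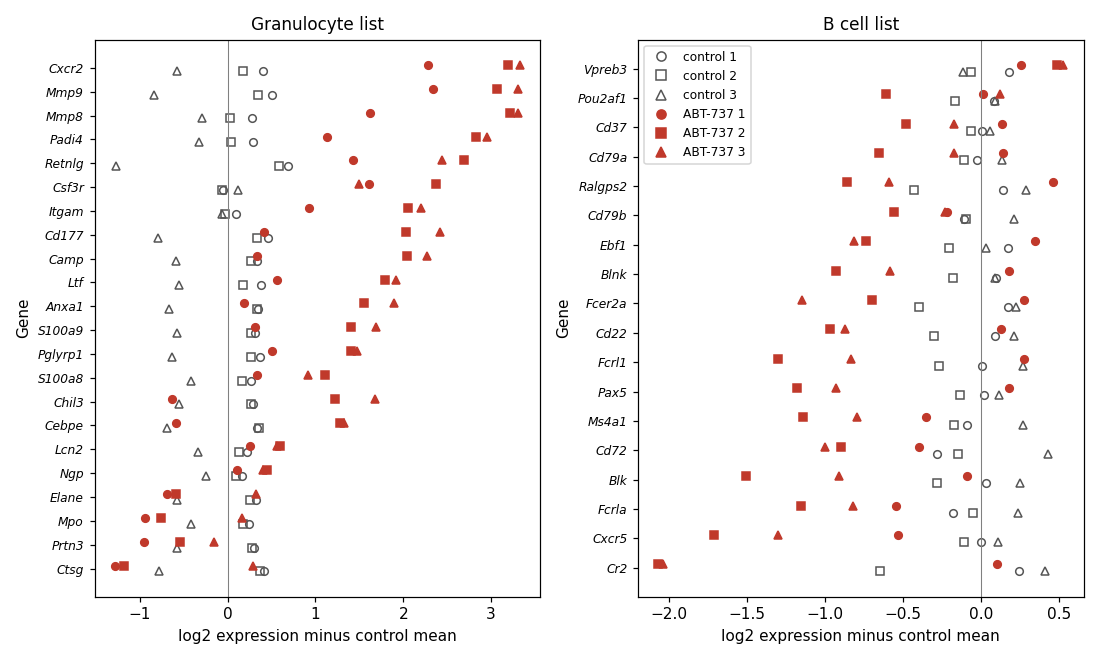
Each point is the log2 expression of 1 gene in 1 mouse minus the mean of the 3 controls, for the measured granulocyte genes (left) and B cell genes (right). Cxcr2, Mmp9 and Mmp8 stand highest on the left and the azurophil genes lowest, and on the right treated mouse 1 often lies among the controls.

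Other myeloid and erythroid lists were higher as well. Monocyte and macrophage genes had a median of 0.34 (16 of 22 higher), and 4 passed adjusted over the list alone and 0 over all genes. These were Hmox1, which degrades haem, at 1.13 (SE 0.18), the iron exporter Slc40a1 at 1.25 (SE 0.24), the lipopolysaccharide co-receptor Cd14 at 1.26 (SE 0.30) and Cd68 at 0.90 (SE 0.24). That number was 9 without control mouse 3, 2 without control mouse 1 or treated mouse 2, and 1 without treated mouse 3, and the median was 0.54 without control mouse 3, 0.56 without treated mouse 1 and 0.23 without control mouse 2. All 18 erythroid genes had higher means, with a median of 0.87, but the list mean was -0.54 in treated mouse 1 against 1.28 and 1.87 in treated mice 2 and 3. Its median was 1.55 without treated mouse 1 and 0.36 without treated mouse 3, and 0 members passed over the list alone. Megakaryocyte and platelet genes had a median of 0.40 (13 of 16 higher), with Cd9 at 1.25 and the thrombin receptor F2rl2 at 1.64 passing over the list alone. Their median was 0.64 without treated mouse 1 and 0.26 without control mouse 2. The exact permutation test of the list mean gave p = 0.2 for monocyte, 0.4 for erythroid and 0.2 for megakaryocyte genes. The adjusted p with an estimated correlation was 0.590 for each of these 3 lists.

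B cell genes were lower, 17 of 18 measured, with a median of -0.55. Adjusted over the list alone, Cxcr5 and Fcrla passed, the latter at -0.84 (SE 0.19), and Ms4a1, which encodes CD20, stood at -0.76 (SE 0.22). The list mean was 0.02 in treated mouse 1, within the range of the controls, and -0.94 and -0.70 in treated mice 2 and 3. Its median was -0.92 without treated mouse 1 and -0.32 without treated mouse 2. Plasma cell genes were higher, 12 of 13, with a median of 0.31, and Sdc1, the plasma cell surface marker CD138, rose by 1.38 (SE 0.29) and Tnfrsf17, the receptor BCMA, by 1.40 (SE 0.36) over the list alone. The plasma cell median was 0.16 without treated mouse 3. All 5 measured MHC class II presentation genes were lower, with a median of -0.27. That call ended without treated mouse 3, at -0.10, and without control mouse 3, at -0.16. The exact permutation test of the list mean gave p = 0.2 for B cell, 0.1 for plasma cell and 0.2 for MHC class II genes. The adjusted p with an estimated correlation was 0.590 for each of these 3 lists. In the T cell list (median -0.11, 9 of 23 higher), which was not called, the costimulatory receptor Icos fell by 1.17 (SE 0.24) over the list alone. Camera called that list lower without control mouse 3, at -0.19, or treated mouse 1, at -0.22, and its median was -0.01 without control mouse 1 or treated mouse 3 and -0.07 without treated mouse 2.

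**Figure D2:**
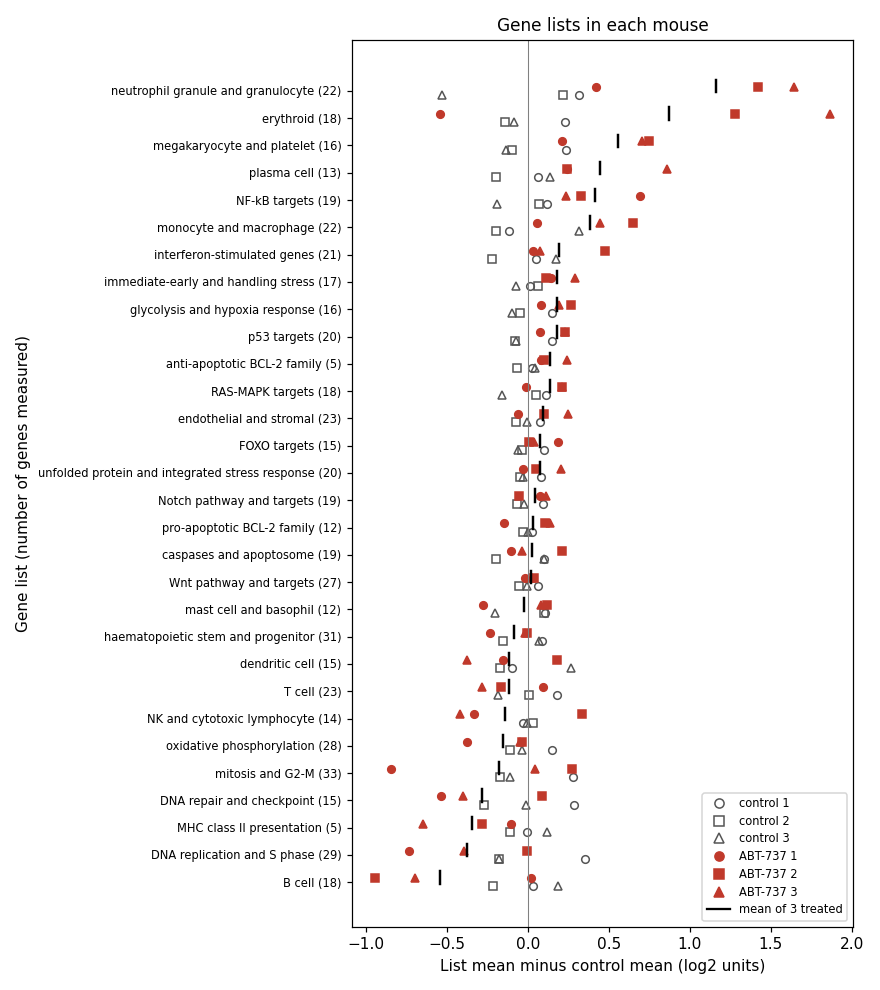
Each row is 1 gene list with its number of measured genes, and each point is the mean log2 expression of that list in 1 mouse minus the mean of the 3 controls. Treated mouse 1 lies at 0.42 for granulocyte genes and -0.54 for erythroid genes, where treated mice 2 and 3 lie above 1.

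Proliferation genes had lower means. All 29 DNA replication genes were lower, with a median of -0.37, and examples were the helicase subunits Mcm3 at -0.62 (SE 0.20), Mcm5 at -0.60 (SE 0.20) and Mcm2 at -0.53 (SE 0.17). Members varied together (estimated correlation 0.79), so they are not 29 separate observations. The list mean was -0.73, -0.00402 and -0.40 in treated mice 1, 2 and 3 and 0.35, -0.18 and -0.18 in the controls. Treated mouse 2 thus lay above control mice 2 and 3. The replication median was -0.21 without treated mouse 1, -0.22 without control mouse 1 and -0.58 without treated mouse 2. All 15 DNA repair and checkpoint genes were lower (median -0.32), and that call ended without treated mouse 1, control mouse 1 or treated mouse 3, at -0.15, -0.14 and -0.23. The mitosis list, with 29 of 33 lower and a median of -0.18, was not called. Camera called it lower without treated mouse 2, at -0.44, treated mouse 3, at -0.30, or control mouse 3, at -0.24, while its median was -0.28 without control mouse 2, -0.04 without control mouse 1 and 0.16 without treated mouse 1. Oxidative phosphorylation genes had a median of -0.19 (25 of 28 lower), and the call ended without treated mouse 1, at -0.09, or control mouse 1, at -0.11. The adjusted p with an estimated correlation was 0.590 for replication, 0.641 for repair and for oxidative phosphorylation. The exact permutation test of the list mean gave p = 0.3 for replication and for repair, 0.8 for mitosis and 0.5 for oxidative phosphorylation. No gene of these 4 lists passed over its list alone by limma. An unadjusted p under 0.05 was found for 7 replication genes, all lower, 0 repair genes, 0 mitosis genes and 3 oxidative phosphorylation genes. Of the latter, 2 were lower and 1, Ndufa1, was higher at 0.50 (SE 0.19).

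Survival genes showed small differences. Bcl2 stood at 10.91 ± 0.08 in the controls and 10.99 ± 0.49 in the treated mice (SD, n = 3 each), Mcl1 differed by 0.14 (SE 0.14) and Bcl2l2, which encodes BCL-W, by -0.04 (SE 0.13). Bcl2l1, which encodes BCL-XL, was higher by 0.52 (SE 0.21, adjusted p = 0.468 by limma), or 0.32 without treated mouse 3, and treated mouse 1, at 7.45, lay within the controls. Nras differed by 0.09 (SE 0.17). Whether the array entries for Bcl2 and Nras also report the transgenes was not tested here, so these values need not reflect transgene expression. List medians were 0.08 for the anti-apoptotic BCL-2 family (4 of 5 higher), 0.04 for the pro-apoptotic family (9 of 12 higher) and -0.01, with a mean of 0.02, for caspases and apoptosome (9 of 19 higher), and none of the 3 was called. By the exact permutation test of the list mean, p was 0.1, the smallest possible, for the anti-apoptotic family and 0.9 for the pro-apoptotic family. With an estimated correlation their adjusted p values were 0.590 and 0.778. Bcl2 and the medians of both BCL-2 families turned negative when arrays were centred, and the anti-apoptotic median was 0.03 without control mouse 3 and 0.04 without treated mouse 2. The p53 target list was called higher with a median of 0.11 (14 of 20 higher; exact permutation p = 0.2), and Mdm2, the ubiquitin ligase that restrains p53, was higher by 0.50 (SE 0.12). Its adjusted p with an estimated correlation was 0.590, and the call ended without control mouse 2, control mouse 3, treated mouse 1 or treated mouse 2, where the medians were 0.06, 0.11, 0.22 and 0.09.

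Stem cell and signalling lists were mostly not called. Stem and progenitor genes had a median of -0.10 (10 of 31 higher), with Cd34 at -0.69 (SE 0.25), the receptor Flt3 at -0.72 (SE 0.25), Hoxa9 at -0.36 (SE 0.12) and Kit at 0.04 (SE 0.19). The largest difference in the list was higher, Erg at 0.84 (SE 0.34). Groups overlapped for Cd34, Flt3 and Erg. At an unadjusted p under 0.05 by limma, 4 members of the list were lower and 1 was higher, and none passed over the list alone. Camera called that list lower without control mouse 2, at -0.15, and its median was -0.04 without treated mouse 1 and -0.16 without treated mouse 3. Medians were 0.01 for the Wnt list (14 of 27 higher; higher by camera and lower by fry), 0.04 for Notch (10 of 19) and 0.13 for FOXO targets (9 of 15). The Notch median was 0.12 without treated mouse 1, 0.018 without control mouse 2 and 0.005 without treated mouse 3, and the FOXO median 0.07 without control mouse 2 and 0.06 without control mouse 3. Kit and the Wnt and Notch medians turned negative under quantile normalization and under centring. Over their lists alone, Numb, an inhibitor of Notch, at 0.80 and Txnip at 0.70 passed. RAS-MAPK targets had a median of 0.35 (10 of 18 higher), which was 0.19 without treated mouse 2 and 0.21 without control mouse 3 or treated mouse 3, and over the list alone 4 passed, Ier3 at 1.29 and Spry4 at 0.67 higher and Myc at -0.95 and Egr2 at -0.72 lower. That number was 8 without treated mouse 1, 2 without treated mouse 2 or 3, 1 without control mouse 2 or 3 and 0 without control mouse 1. NF-kB targets were called higher with a median of 0.18 (13 of 19 higher; adjusted p = 0.590 with an estimated correlation; exact permutation p = 0.1, the smallest possible). Over the list alone 5 passed, with the neutrophil chemokine Cxcl2 at 2.31 (SE 0.39), the prostaglandin synthase Ptgs2 at 1.82 (SE 0.32), Ccl4 at 1.05 and Ccl3 at 0.66 higher and Cd83 lower, and over all genes 0 passed. Without treated mouse 1 the median was 0.06 and the call ended. The median was 0.31 without control mouse 1, 0.29 without treated mouse 2 and 0.35 without treated mouse 3, and 3 genes passed over the list alone without control mouse 1 and 8 without treated mouse 2.

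Immediate-early genes were called higher (median 0.28, 14 of 17 higher, adjusted p = 0.590 with an estimated correlation), although the heat-shock gene Hsph1 was lower at -1.12 (SE 0.26). By the exact permutation test of the list mean, p was 0.1, the smallest possible, for immediate-early genes. It was 0.5 for interferon-stimulated genes and 0.2 for glycolysis and hypoxia genes. Interferon-stimulated genes were called at a median of 0.21 (15 of 21 higher, adjusted p = 0.641 with an estimated correlation), and the call ended without control mouse 1 or 2, at 0.20 and 0.06, or treated mouse 1 or 2, at 0.30 and 0.14. Glycolysis and hypoxia genes were called at 0.06 (9 of 16 higher, adjusted p = 0.590 with an estimated correlation), with the lactate transporter Slc16a3 at 1.29 and Bnip3l at 0.51 passing over the list alone. Under quantile normalization and centring that median was -0.0024 and -0.02, and without control mouse 1 it was 0.13. The call ended without control mouse 2, at 0.03, control mouse 3, at 0.06, treated mouse 1, at 0.02, or treated mouse 2, at 0.08. Lists not called were the unfolded protein response (median 0.02), NK cells (-0.20), dendritic cells (-0.09), mast cells and basophils (-0.10) and endothelial and stromal genes (0.00667), and the first and last of these turned negative under both scalings. Without treated mouse 2, camera called the NK list lower, at -0.48, and the dendritic list lower, at -0.10. The NK median was -0.11 without control mouse 3, -0.05 without treated mouse 1 and -0.04 without treated mouse 3. The dendritic median was -0.25 without control mouse 2, 0.16 without control mouse 3, -0.05 without treated mouse 1 and -0.01 without treated mouse 3. The mast cell median was -0.02 without treated mouse 1 and -0.16 without control mouse 3. Hdc, the histamine-forming enzyme, passed over the mast cell list alone at 2.02 (SE 0.42), while the basophil protease Mcpt8 stood at -0.89 (SE 0.28).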

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

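The setting with all table entries and the 4 lists counted over the list alone were chosen after seeing the data, and the other settings were fixed before. No paired analysis was possible because the replicate numbers were given in accession order and the labels carry only mouse numbers that differ between groups. Adjusted calls by limma, 0 with all genes tested, were 14 without the dimmest signals, 2 with array weights and 0 to 510 with 1 mouse left out. The 14 were not due to fewer tests alone, since the unchanged p values adjusted over the 10833 genes left gave 0. The 510, found without treated mouse 1, held 458 higher and 52 lower genes. Other settings gave 0. The 660 genes at 1.5-fold were 1023 over all entries, 224 at 2-fold and 431 to 1231 with 1 mouse left out. The 504 higher were 819, 194 and 310 to 955. The 156 lower were 30 at 2-fold, 241 after quantile normalization, 303 after centring and 98 to 318 with 1 mouse left out. The 15 lists were 0 with an estimated correlation and 0 by fry.

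Counts over a list alone, with 1 mouse left out, were 6 to 18 for granulocyte genes, 1 to 9 for monocyte genes, 3 to 8 for NF-kB targets and 0 to 8 for RAS-MAPK targets. With a sex covariate, which equals leaving out control mouse 3, they were 8, 9 and, for RAS-MAPK, 1. NF-kB gave 8 with array weights and RAS-MAPK 2 after quantile normalization. Reversals were mostly of values near 0, and their cause was not tested. After quantile normalization and after centring, medians were -0.025 and -0.045 for pro-apoptotic genes, -0.047 and -0.077 for Wnt, -0.015 and -0.043 for Notch, -0.061 and -0.067 for the unfolded protein response, -0.0024 and -0.023 for glycolysis, -0.043 and -0.080 for endothelial genes, and Kit was -0.044 and -0.047. After centring, the anti-apoptotic family and Bcl2 were both -0.01. With the sex covariate, caspases were 0.085, Wnt -0.005, dendritic cells 0.16 and Bcl2l2 0.025. With array weights the unfolded protein response was -0.0079 and Kit -0.095, and without shared members the former was -0.042. With 1 mouse left out the ranges were -0.038 to 0.048 for Wnt, -0.16 to 0.085 for caspases, -0.25 to 0.16 for dendritic cells, -0.033 to 0.055 for endothelial genes, -0.44 to 0.16 for mitosis, -0.042 to 0.11 for pro-apoptotic genes, -0.015 to 0.055 for the unfolded protein response, -0.17 to 0.31 for Bcl2, -0.15 to 0.025 for Bcl2l2, -0.14 to 0.18 for Kit and -0.04 to 0.21 for Nras.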

Other observations

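The tests of granulocyte stage, of B cell dilution, of replication in 1 treated mouse and of sex as the whole cause were chosen only after the result was seen. The NRF2 and other early granulocyte genes were chosen after the patterns were seen, before these members were looked at, and the germinal centre tests were also chosen after values had been seen. Hmox1 and Slc7a11, both targets of the oxidative stress factor NRF2, were among the genes with the smallest p. Of 14 other NRF2 targets, none in the fixed lists, 12 were higher, with a median of 0.325 log2, or 0.54 without treated mouse 1. Their mean was 0.00976 in treated mouse 1, within the controls, and 0.52 and 0.66 in treated mice 2 and 3 (exact permutation p = 0.2, unadjusted p = 0.158 with an estimated correlation). A shared NRF2 response may exist, but these mice do not settle it. Granulocyte list means ran in the same order, at 0.42, 1.42 and 1.65 in treated mice 1, 2 and 3, and the NRF2 values were not separated from them.

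Cxcr5 and Icos, members of the B cell and T cell lists that also act in the germinal centres where B cells are selected, were among the lowest. Of 16 other germinal centre genes 13 were lower, with a median of -0.233 (exact permutation p = 0.1, unadjusted p = 0.092 with an estimated correlation). The higher ones were Bcl6 at 0.41, Bach2 at 0.04 and Cd40lg at 0.03. That median was -0.14 without control mouse 1, -0.35 without control mouse 3 and -0.38 without treated mouse 1. Of the 16, 5 stood in fixed lists and had been seen. Of the 11 others 10 were lower, with a median of -0.323. Their means were -0.06, -0.51 and -0.37 in the treated mice and 0.27, -0.08 and -0.19 in the controls, so the groups overlapped (exact permutation p = 0.3, unadjusted p = 0.169 with an estimated correlation), and the median was -0.15 without control mouse 1. Fewer germinal centre cells may lie behind these values, but the mice do not settle it, and B cell genes were lower too.

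Granulocyte genes were higher in treated mice. Their median of 1.17 stayed at 92.6% of its value or more under quantile normalization or centring. As array medians ran only from 6.86 to 7.14, these scalings could hardly have halved it, so that outcome was largely fixed beforehand. A difference in overall array level is too small to account for 1.17. The unknown normalization behind the deposited values was not tested. A like rise of granulocytes of every stage was examined with 4 measured early granulocyte genes outside the fixed lists, Ms4a3, Ctsc, Cebpa and Clec12a. Other myeloid cells also express the last 3. The mean difference of the 4 was -0.0167 (SE 0.37), with -0.74, 0.28 and 0.42 in the treated mice and 0.07, 0.07 and -0.13 in the controls. Single genes ran from -0.44 for Ms4a3 to 0.48 for Clec12a, and the median from -0.23 to 0.17 with 1 mouse left out. The granulocyte list minus these genes was 2.05 to 2.14 in treated mice and 0.51 to 1.15 in controls (difference 1.18, SE 0.20, exact permutation p = 0.1, the smallest possible). On average these 4 genes did not rise, with 1 higher and 3 lower. The granulocyte list was already known to stand highest when it was set against them, so its excess over them cannot decide. With so wide an SE and 3 genes shared with other cells, a rise of every stage was not excluded. The 4 azurophil genes, seen to be lower before they were tested, had a mean of -0.528 (SE 0.46, exact permutation p = 0.2), with -0.97, -0.77 and 0.15 in the treated mice and 0.32, 0.27 and -0.59 in the controls. Control mouse 3 alone had low Y-linked signal, and without it the median was 73.3% of its value; 7 genes still passed higher over the list alone, but Prtn3 passed lower, so a part for that mouse or its sex could not be excluded. More granulocytes of every stage, more late granulocytes in the selected cells and higher expression per cell are candidate explanations that were not separated.

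B cell genes were lower in treated mice. Whether a lower share of B cells raised all other cells alike was not settled. The granulocyte list was already known to stand highest when it was set against the T cell list, so that comparison cannot decide. The granulocyte list exceeded the T cell list by 1.28 log2 (SE 0.52, exact permutation p = 0.1, the smallest possible), or 0.96 without treated mouse 3 and 1.76 without treated mouse 1, and the lowest treated mouse was at 0.97 against 0.86 in the highest control. T cell minus B cell scores were -1.02, -0.32 and -0.68 in the treated mice and -0.95, -0.88 and -1.46 in the controls, a difference of 0.42 (SE 0.27, exact permutation p = 0.3). A lower share of B cells, a change in B cells themselves or a rise in granulocytes may account for the values. These scores do not separate them.

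Replication genes were lower in treated mice. Without treated mouse 1 the median kept 56.3% of its value, so whether that mouse carried the difference cannot be told apart from a difference shared by the group. In treated mouse 2 the list mean was near 0. A lower rate of division after the drug could give the same replication values and was not tested. The mitosis list did not separate the groups. Its means were -0.85, 0.27 and 0.04 in treated mice 1, 2 and 3 and 0.28, -0.17 and -0.11 in the controls (exact permutation p = 0.8).

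The 6 mice make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 adjusted calls, as did all 10 splits, and the highest of the others was 0. It gave 1516 genes at an unadjusted p under 0.05 against at most 1279 in another split. At 1.5-fold it gave 660 genes against at most 448, and it gave 15 lists against at most 12. For each of these 3 counts, 1 of 10 splits, the real one, was as large.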
